A study of Mus musculus with 36 samples.

How the data were processed

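Total RNA from the livers of 36 mice had been labelled with biotin and hybridised to 1-colour Affymetrix arrays, with 1 array per mouse. Per the submitters' processing notes, the deposited intensity values are MAS5 signals per probe set, with a version not given in the sources used here. MAS5 sets the perfect-match probes of a probe set against their mismatch partners and gives 1 signal. The values were on a linear scale, and the mean of each array, with 2% trimmed at each end, was 150 before any change made here, so they were used as deposited. No detection calls were used here. Each mouse has its own number in the labels, and the numbers do not pair mice between times or strains. The groups were the 4 strains at 0 h, 3 h and 6 h, with 3 mice each.

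A small offset was added to every signal before the log2 was taken: 2.77, the 10th percentile of all values. Of 45101 probe sets, 64 controls were left out, 34945 carried 1 gene symbol, 932 carried several genes and 9160 carried none. A gene was represented by the probe set with 1 symbol and the highest mean log2 signal over the 36 arrays. Probe sets whose name marks them as able to bind other transcripts were passed over unless a gene had no other. This gave 18193 genes. A gene was tested if at least 3 arrays lay above the median of all values, 30.8, which left 14057. Probe sets without a single gene name were counted apart. No genome was used, so no coordinates are given.

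Group means of the 12 groups were fitted across all 36 arrays with limma 3.58.1 in R 4.3.3, with moderated tests and 24 residual degrees of freedom. The Benjamini-Hochberg adjustment was made over the genes tested in each comparison, with a threshold of 0.05. The comparisons were the change from 0 h to 3 h, from 0 h to 6 h and from 3 h to 6 h as the mean of the 4 strains; the change in each strain; SJL against the mean of the other 3 strains at 0 h; the change in SJL against the mean change of the other 3; and a moderated F test for any difference between strains in the change. The contrast of 1 strain with the mean of the other 3 was also computed for SMJ, DBA and C57. All p values are two-sided. The labels give no batch, and none was fitted.

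The samples, the comparisons, the 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for those said to have been added later. The lists held 390 genes, of which 344 were tested. They covered NRF2 targets, acetaminophen bioactivation and conjugation, the methionine cycle and sulfur amino acids, immediate early genes, the endoplasmic reticulum and integrated stress response, heat shock proteins, p53 targets, cytokines with chemokines and adhesion molecules, acute phase proteins, fatty acid oxidation and PPARA targets, fatty acid synthesis, cholesterol synthesis, glucose production and use, bile acid synthesis and transport and the circadian clock. Markers of pericentral and periportal hepatocytes, hepatocyte secreted proteins, neutrophils, Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, lymphocytes, bile duct cells and erythroid cells made up the rest. Each list was tested in 5 comparisons, or 125 pairs, with limma's camera and its preset correlation between genes, and the adjustment was made over the pairs. Camera was repeated with the correlation estimated for each list. A list for which only an adjusted p with an estimated correlation is given had passed camera with the preset correlation. Where a list's adjusted p names no test, it is that of camera with the preset correlation. Fry tested whether a list's genes moved, on balance, 1 way, without comparing them with other genes.

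The genes named for the means of the 4 strains at 3 h and 6 h were the 10 with the largest rise and the 10 with the largest fall past the threshold that went the same way in each strain. For the change from 3 h to 6 h it was the 3 largest each way by the same rule, and for each strain alone the 2 largest each way. For SJL at 0 h it was the 10 largest each way with all 3 SJL arrays outside the range of the other 9. For the difference in response it was the 10 largest each way with SJL outside the range of the other strains, and for the F test the 5 with the smallest p. Up to 4 members of each list with the smallest p in each comparison, and Bhmt2, Bhmt, Cyp2e1, Gclc, Gclm, Hmox1, Nqo1 and Alb, were added. Genes without an official name were passed over except in lists. In all 317 genes were named by the rule, and not all are mentioned.

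The procedure was tested on simulated data with changes of known size placed in 200 genes per fold. Each gene was drawn with the same spread in all 12 groups, so a group more variable than the others was not simulated. For the mean change at 6 h it recovered 62.5% of 1.5-fold, 85% of 2-fold and 98% of 4-fold changes, with 3.16% false calls. For SJL at 3 h against 0 h it recovered 23%, 61.5% and 84.5%, with 3.98% false calls. For SJL against the others at 0 h it recovered 39.5%, 68% and 90%, with 5.05%, and for the difference in response at 3 h 24.5%, 50.5% and 74%, with 4.79%. A simulated list of 20 genes raised 1.5-fold had a camera p of 6.41e-54, and 5 of 200 unchanged lists had a p under 0.05. The simulated genes were uncorrelated, whereas the real lists had estimated correlations up to 0.696, so these list values do not measure false calls among the real lists.

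The alternatives were an offset of 1 or of the 25th percentile, 8.78; no filter, or a filter at the 75th percentile, 127; quantile normalization; division of each array by its own 75th percentile; every probe set tested; array weights; a prior variance with a trend; only the arrays of the groups compared; and each array of the groups compared left out in turn. Leaving out each array of the other groups in turn, those of SMJ56 and SJL39 together, and that of SJL39 with the lists recomputed, were added after the data had been seen. Where an omission left 2 mice in a group, the fit pooled the spread over all groups. Under each scaling the median change of all genes lay between -0.1 and 0.1. Other splits of the arrays were drawn with a fixed seed, 100 where more were possible. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.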

Results

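Gene expression was measured in mouse liver on 36 Affymetrix arrays of total RNA, with 1 mouse per array. The mice belonged to 4 strains labelled SJL, SMJ, DBA and C57, were fasted overnight and were given acetaminophen, a painkiller that injures the liver at high dose, as a single injection of 300 mg/kg into the abdomen. Livers were taken before the dose (0 h) and 3 h and 6 h after it, from 3 different mice for each strain and time, which made 12 groups of 3. A mouse is named by its strain and number, as SJL39. The series names SJL as resistant to the liver injury and the other 3 strains as sensitive. No group given vehicle alone was part of the series at 3 h or 6 h, so time of day and length of fasting moved together with the time after the dose. Of 18193 genes with a probe set of their own, 14057 were tested. The 36 pairs of arrays from the same group had correlations between 0.916 and 0.964 across genes, and the number of arrays limits the precision of every value. Changes are given on the log2 scale with the standard error (SE) from limma over all 36 arrays, adjusted p values are limma's, and levels are MAS5 signals as mean ± SD of 3 mice.

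The first comparison asked how the liver had changed 3 h after the dose, as the mean of the 4 strains. Immediate early genes and targets of the antioxidant regulator NRF2 were among those that rose. Atf3, a transcription factor induced by many kinds of cell stress, rose 35.3-fold (log2 change 5.14 ± 0.30, adjusted p = 5.37e-12), and Hmox1, the heme-degrading enzyme induced by oxidative stress, rose 13.2-fold (3.72 ± 0.26, adjusted p = 1.18e-10). Atf3 reached 3944 ± 1880 in SJL and 1013 ± 62.6 in C57 from 36.2 ± 3.52 and 52.7 ± 35.1 at 0 h. In all, 444 genes were higher and 568 lower, of which 94 were higher and 35 lower by at least 2-fold.

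Of the 20 immediate early genes tested, which are switched on within minutes of a stimulus without new protein synthesis, 18 rose at 3 h (18 adjusted over the list alone). Fos and Jun, the subunits of the AP-1 transcription factor, rose by 4.25 ± 0.47 and 3.13 ± 0.34, Egr1 by 3.72 ± 0.38, and Btg2, a growth-restraining gene, by 2.97 ± 0.18. The list passed limma's camera test (adjusted p = 6.24e-53, and 0.000319 with an estimated correlation). Gadd45a, a growth arrest gene of the same list, rose by 3.81 ± 0.27. Outside the list Arid5a, an RNA-binding protein that stabilises cytokine messages, rose by 2.84 ± 0.28. Of 23 target genes of NRF2, the regulator of antioxidant defence, 10 rose and none fell (16 adjusted over the list alone). Among them were Osgin1 at 1.79, Srxn1, which repairs oxidised peroxiredoxins, at 1.63 and Gclc, the catalytic subunit of glutathione synthesis, at 1.05. This list also passed (adjusted p = 1.26e-17, and 0.00192 with an estimated correlation).

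Several further lists were higher at 3 h by camera but not when the correlation between their genes was estimated. Of 18 genes of the endoplasmic reticulum and integrated stress response, 6 rose (8 adjusted over the list alone; adjusted p = 0.092 with an estimated correlation). Ddit3, a pro-apoptotic transcription factor, led at 2.84, followed by Chac1, which degrades glutathione, at 2.58. Of 13 heat shock proteins, 7 rose (9 adjusted over the list alone), among them the chaperones Hspa1a at 2.20 and Dnajb1 at 2.00 (adjusted p = 0.0777 with an estimated correlation). Of 21 cytokines, chemokines and adhesion molecules, 4 rose (9 adjusted over the list alone), including the neutrophil attractants Cxcl2 at 3.10 and Cxcl1 at 2.35 (adjusted p = 0.12 with an estimated correlation). Beside them, 1 of 9 neutrophil markers rose (4 adjusted over the list alone; camera adjusted p = 0.00959, and 0.251 with an estimated correlation), the collagenase Mmp8 at 1.05, whose call ended without any 1 of 29 arrays (adjusted p up to 0.1, without DBA115). Of 14 genes of fatty acid synthesis, 2 rose (5 adjusted over the list alone), with Thrsp, a lipogenic nuclear protein, at 2.06 (adjusted p = 0.126 with an estimated correlation). Leaving out single arrays ended the calls of 2 of the 7 heat shock genes, 1 of the 4 cytokine genes and 1 of these 2. Of 13 p53 target genes, 3 rose (3 higher and 1 lower adjusted over the list alone). The list as a whole missed the threshold in camera (adjusted p = 0.0616, and 0.155 with an estimated correlation) and passed it upward in fry (adjusted p = 0.00483). The 3 genes were Mdm2, the p53 ubiquitin ligase, at 0.85, Trp53inp1 at 1.29 and the cell cycle inhibitor Cdkn1a at 1.05.

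The falls at 3 h were smaller. Hsd3b3, a steroid dehydrogenase of the liver, fell by 1.82 on the log2 scale (SE 0.27, adjusted p = 5.31e-05). Rbmxl2, an RNA-binding protein, fell by 1.92, Rab3a, a vesicle GTPase, by 1.43, Clec2d, a lectin, by 1.35 and Arrdc3, an arrestin-domain protein, by 1.19. The p450 enzyme Cyp2e1, which turns acetaminophen into its reactive quinone imine, had a log2 change of 0.12 (adjusted p = 0.606). None of the 13 genes of acetaminophen bioactivation and conjugation passed limma's test (1 higher adjusted over the list alone, camera adjusted p = 0.0565, fry adjusted p = 0.0591), with 2 of them at an unadjusted p under 0.05. Of 11 markers of pericentral hepatocytes, the cells around the central vein where acetaminophen injury begins, only the transcription factor Tbx3 fell at 3 h over all genes, by 0.78 (3 lower adjusted over the list alone, adjusted p = 0.223 with an estimated correlation). When each array was divided by its own 75th percentile, the 3 h split turned to 588 higher and 396 lower.

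The same question at 6 h gave a broader response, with 1786 genes higher and 2872 lower, of which 310 were higher and 137 lower by at least 2-fold. Immediate early genes and NRF2 targets were higher, and markers of pericentral hepatocytes were lower. Atf3 stood 69.5-fold above 0 h (6.12 ± 0.30, adjusted p = 2.68e-14), whereas Slc1a2, a glutamate transporter of pericentral hepatocytes, stood 14-fold below it (-3.81 ± 0.34, adjusted p = 2.06e-09). Between 3 h and 6 h itself, 976 genes rose and 1380 fell. The AP-1 subunits Fosb and Fosl1 rose by 2.43 ± 0.31 and 2.30 ± 0.42 and the matrix protein gene Ccn1 by 2.26 ± 0.26. Slc1a2 fell by 2.75 and the p450 genes Cyp2c39 and Cyp2c38 by 2.17 and 1.90.

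**Figure D1:**
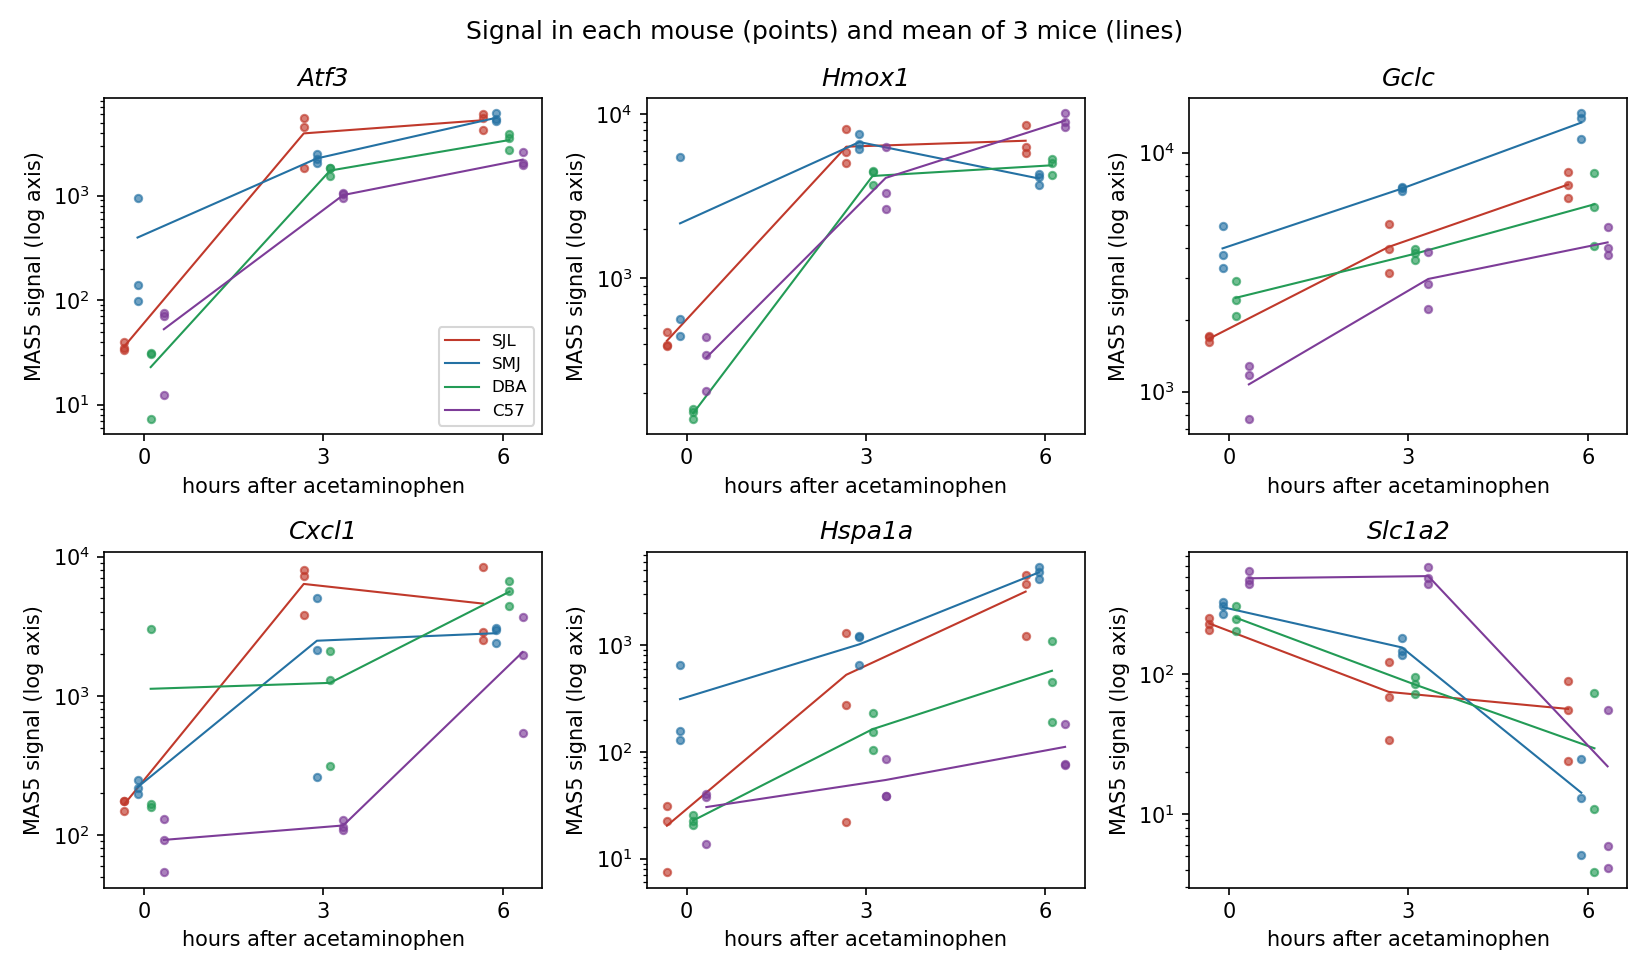
MAS5 signal (log axis) against hours after acetaminophen for Atf3, Hmox1, Gclc, Cxcl1, Hspa1a and Slc1a2 in SJL, SMJ, DBA and C57 mice; points are single mice and lines join the means of 3 mice. Mean Slc1a2 fell from 486.1 at 0 h to 21.9 at 6 h in C57, and the highest SMJ point for Atf3 at 0 h is SMJ56 at 953.

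At 6 h all 20 immediate early genes had risen (20 adjusted over the list alone; adjusted p = 0.00271 with an estimated correlation). Fos rose by 6.03 ± 0.47, Maff, a small MAF transcription factor, by 4.74 ± 0.18, Egr1 by 4.63 ± 0.38 and Jun by 4.35 ± 0.34. H3f3b, which encodes a replacement histone, rose by 4.15 ± 0.32. Of the 23 NRF2 target genes, 16 rose (16 adjusted over the list alone; adjusted p = 0.00626 with an estimated correlation), with Osgin1 at 2.71, Gclc at 1.79, the thioredoxin reductase Txnrd1 at 1.45 and Nqo1, a quinone reductase, at 0.76. All 13 heat shock proteins rose (13 adjusted over the list alone; adjusted p = 0.0588 with an estimated correlation), from Hspa1a at 4.33 ± 0.45 and Dnajb1 at 3.26 ± 0.22 to a list median of 0.93. That was the mean of the strains: 13, 11 and 6 of the 13 rose in SJL, SMJ and DBA, but only Dnajb1 in C57, where the list median was -0.06 and the lowest change was that of Hspa1b, -1.62, which did not pass (adjusted p = 0.0857). In the endoplasmic reticulum and integrated stress response 11 of 18 genes rose (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Ddit3 stood at 3.39 and Ppp1r15a, which restores translation after stress, at 1.80 above 0 h. Among p53 target genes 5 of 13 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0731 with an estimated correlation), with Cdkn1a at 1.61 and Mdm2 at 1.40.

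Of the 21 cytokines, chemokines and adhesion molecules, 14 rose at 6 h (17 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation). Cxcl2 rose by 4.46 ± 0.41, Cxcl1 by 4.0 ± 0.46, Socs3, a brake on cytokine signalling, by 2.47 and Ccl2, a monocyte attractant, by 2.43. Of 9 neutrophil markers 6 rose (7 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation), with the calprotectin subunits S100a8 and S100a9 at 2.58 and 2.53. Of 13 Kupffer cell and macrophage markers 5 rose (5 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation), with Cd14, the endotoxin co-receptor, at 2.61 and Cd68 at 0.96. Of 11 endothelial markers 6 rose (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.102 with an estimated correlation), with Lyve1 at 0.64 and Pecam1 at 0.56. None of 8 lymphocyte and 3 erythroid markers passed limma's test at 6 h, over all genes or adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.583 and 0.368, fry adjusted p = 0.48 and 0.114). The 3' to 5' signal ratio of actin, a sign of RNA integrity, moved with time in 3 strains. Its group means at 0 h, 3 h and 6 h were 1.71, 1.46 and 1.45 in SJL, 1.57, 1.44 and 1.35 in SMJ, 1.77, 1.60 and 1.44 in DBA, and 1.64, 1.58 and 1.67 in C57. The same ratio of Gapdh did not follow it in each strain. From 0 h to 6 h it went from 0.7655 to 0.7147 in SJL, 0.7188 to 0.746 in SMJ, 0.7214 to 0.7237 in DBA and 0.7663 to 0.779 in C57.

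Of the 11 pericentral hepatocyte markers, 10 fell at 6 h (10 adjusted over the list alone; adjusted p = 0.00907 with an estimated correlation), with a list median of -1.31. Beside Slc1a2, the ornithine aminotransferase Oat fell by 2.12 (SE 0.14, adjusted p = 1.08e-11), the ammonium transporter Rhbg by 1.74, Lect2, a secreted chemotactic protein, by 1.95, glutamine synthetase Glul by 1.31 and the p450 enzyme Cyp1a2 by 1.25. Other large falls were those of Cyp2c39 (2.33), Cyp2c38 (1.96), the phosphatase Lhpp (1.92), the transcription factor Rfx4 (1.74) and the fatty aldehyde dehydrogenase Aldh3a2 (1.69), each a fall on the log2 scale. These were means of the 4 strains. Within a strain 4 of the 11 pericentral markers fell in SJL, 7 in SMJ, 6 in DBA and 10 in C57, and 1 rose in SMJ. Cyp2e1, which is also pericentral, had a log2 change of -0.03 over the 4 strains (adjusted p = 0.89). It fell by 0.92 in C57 (adjusted p = 0.0051) and rose by 0.63 in SMJ (adjusted p = 0.035). Of 14 genes of bile acid synthesis and transport, 9 fell and none rose (11 lower adjusted over the list alone; adjusted p = 0.102 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -1.59, the uptake transporter Slco1b2 at -0.79 and the bile acid receptor Nr1h4 at -0.68.

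Abundant proteins secreted by hepatocytes went the other way at 6 h, by small amounts that depended on the scaling. Of 12 such genes 10 rose (10 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), with a list median of 0.33 and albumin (Alb) at 0.40. After quantile normalization the list's direction turned and it no longer passed. Of 20 acute phase proteins 11 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.369 with an estimated correlation), with the fibrinogen chains Fga and Fgg at 0.42 and 0.44. After quantile normalization that list had an adjusted p of 0.37. Within a strain the genes that rose were mostly found in SMJ: in SJL, SMJ, DBA and C57 they were 0, 10, 0 and 1 of the secreted proteins and 0, 11, 1 and 0 of the acute phase proteins. The list medians were 0.08, 0.55, 0.27 and 0.37 for the first and 0.14, 0.76, 0.30 and 0.20 for the second, and whether SMJ differed from the others was not tested by list. Of 10 periportal hepatocyte markers 6 rose (6 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation), with Cyp2f2, a p450 enzyme, at 0.47 and arginase (Arg1) at 0.41. With quantile normalization these markers had an adjusted p of 0.698. In the methionine cycle and sulfur amino acid list 4 of 17 genes rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.925). Chdh, which makes betaine from choline, fell by 0.75, and Csad, which makes the taurine precursor, fell by 1.13. Bhmt, which remethylates homocysteine with betaine, rose by 0.37 but had a change of -0.01 after quantile normalization. Its relative Bhmt2 had a change of -0.18 (adjusted p = 0.126). The gluconeogenic enzyme Fbp1 rose by 0.20, with a change of -0.10 after quantile normalization.

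Each strain was then compared with its own 0 h mice, to see which strains had responded by 3 h and by 6 h. At 3 h SJL had 629 genes higher and 795 lower, against 23 and 1 in SMJ, 148 and 56 in DBA, and 29 and 11 in C57. At 6 h the counts were 515 and 467 in SJL, 1236 and 1773 in SMJ, 678 and 1089 in DBA, and 619 and 823 in C57. Atf3 was among the 2 most increased genes in 7 of these 8 comparisons, from 3.24 in SMJ at 3 h to 7.23 in DBA at 6 h. SJL at 3 h was also marked by Cxcl1 at 5.17 and a fall of 4.62 in G0s2, an inhibitor of fat breakdown, and at 6 h by Hspa1a at 7.06. Slc1a2 fell at 6 h by 4.34 in SMJ, 3.74 in DBA and 5.0 in C57. Its change in SJL was -2.15, which did not pass (limma adjusted p = 0.0535). The copper-dependent monooxygenase-like gene Moxd1 fell by 4.75 in C57 at 6 h, and Serpina7, which encodes the thyroxine-binding globulin, by 3.25 in DBA. At 6 h, 192 genes had changed the same way in all 4 strains, 77 of them downward, where independent lists of these sizes would share 0.0962 genes upward and 0.267 downward. The 4 tests share 1 spread per gene and so are not independent, which makes these 2 values too low as a reference. At 3 h, 9 were higher in all 4 and 0 lower by limma, with 2778 genes at an unadjusted p under 0.05 for the mean of the strains.

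**Figure D2:**
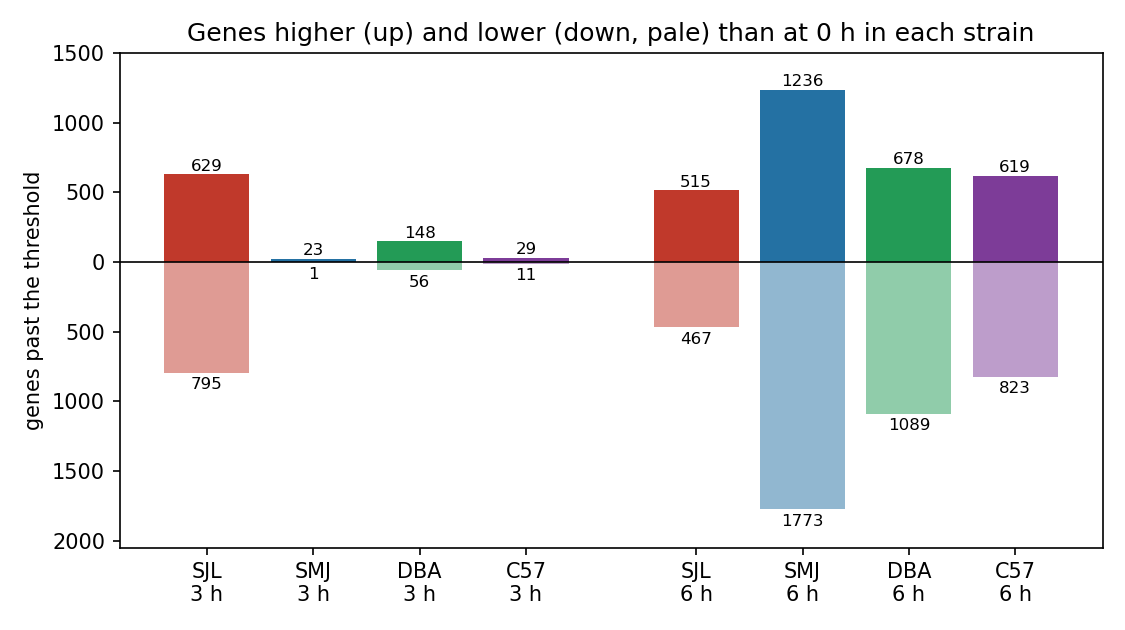
Number of genes higher (bars above 0) and lower (pale bars below 0) than at 0 h, with the adjusted p under 0.05, for each strain at 3 h and 6 h, from 3 mice per group. SJL had 629 higher and 795 lower at 3 h, and SMJ had 1236 higher and 1773 lower at 6 h.

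Counts within a strain rested on few mice and on a spread pooled over all groups. With only the 6 arrays of the groups compared, SJL had 6 genes at 3 h, against 1424 with all arrays, and 311 at 6 h. SJL39 and SJL40 at 3 h had the lowest correlation of any same-group pair, 0.916, so the pooled spread may be too small for this group. SMJ had 0 by limma at 3 h (24 with all arrays, where 1160 genes were at an unadjusted p under 0.05) and 1120 at 6 h, DBA had 92 and 510, and C57 had 13 and 275. Without the array of SJL1 the SJL count became 933 at 3 h, and without SJL1, SJL4 or SJL48 it became 634, 629 or 610 at 6 h. The DBA count became 117 or 135 at 3 h without DBA113 or DBA115, and 1130, 1099 or 1078 at 6 h without DBA113, DBA115 or DBA168. The SMJ count at 3 h became 100 without SMJ56, and 12, 9, 13 or 10 without SMJ57, SMJ58, SMJ95 or SMJ96. Arrays of other groups enter through the pooled spread: without SJL39 the count at 3 h became 44 for SMJ and 66 for C57. The C57 count became 22, 17, 12, 24 or 17 at 3 h without C57181, C57182, C57226, C57230 or C57231, and 863 at 6 h without C57236. The rise of Atf3 in SMJ at 3 h had an adjusted p of 0.20 or 0.165 without SMJ57 or SMJ58, and of 0.0509, 0.0648 or 0.0515 without SMJ95, SMJ96 or SMJ98.

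Before dosing, SJL livers already differed from those of the 3 sensitive strains in 1727 genes, 912 higher and 815 lower, of which 185 and 184 by at least 2-fold. With 1 resistant strain, resistance and strain cannot be told apart; set against the other strains in the same way, SMJ differed in 1352 genes, DBA in 1462 and C57 in 1717. Gstp3, a glutathione transferase of the pi class, was 55-fold higher in SJL (5.78 ± 0.12, adjusted p = 1.65e-22), at 8699 ± 555 against means of 134.5 to 184.7. Cyp7a1 was 6.52-fold higher (2.71 ± 0.45, adjusted p = 0.000178). Dio1, the deiodinase that activates thyroid hormone, was lower by -3.21 ± 0.18 (adjusted p = 1.7e-12), at 237.4 ± 28.2 against means of 2085 to 2450. Without SJL1, SJL2 or SJL4 the count of 1727 became 1015, 1059 or 1092.

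Other genes higher in SJL at 0 h were the flippase gene Atp10d (2.34 ± 0.24), the eosinophil attractant Ccl24 (2.17), the kinase Map2k6 (2.04) and the zinc finger gene Zfp626 (2.51). Lower were Socs2, a brake on growth hormone signalling (-2.91 ± 0.45), Btg2 (-2.84 ± 0.29), Vnn1, a pantetheinase and PPARA target (-2.70 ± 0.34). So were the aldo-keto reductase Akr1e1 (-3.00), Rarres1 (-3.21), Trim12c of the TRIM protein family (-3.83) and the p450 gene Cyp2c37 (-3.75). The lipid droplet protein gene Hsd17b13 was lower by -4.75 ± 0.19 with its more abundant probe set, at 245.5 ± 44.7 in SJL against 6154 to 7340. It was higher by 4.75 with its second probe set, at 1262 ± 250 against 38.7 to 53.8. For genes with a second probe set, that probe set showed the same difference for 56.06% of those lower in SJL and 64.62% of those higher.

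**Figure D3:**
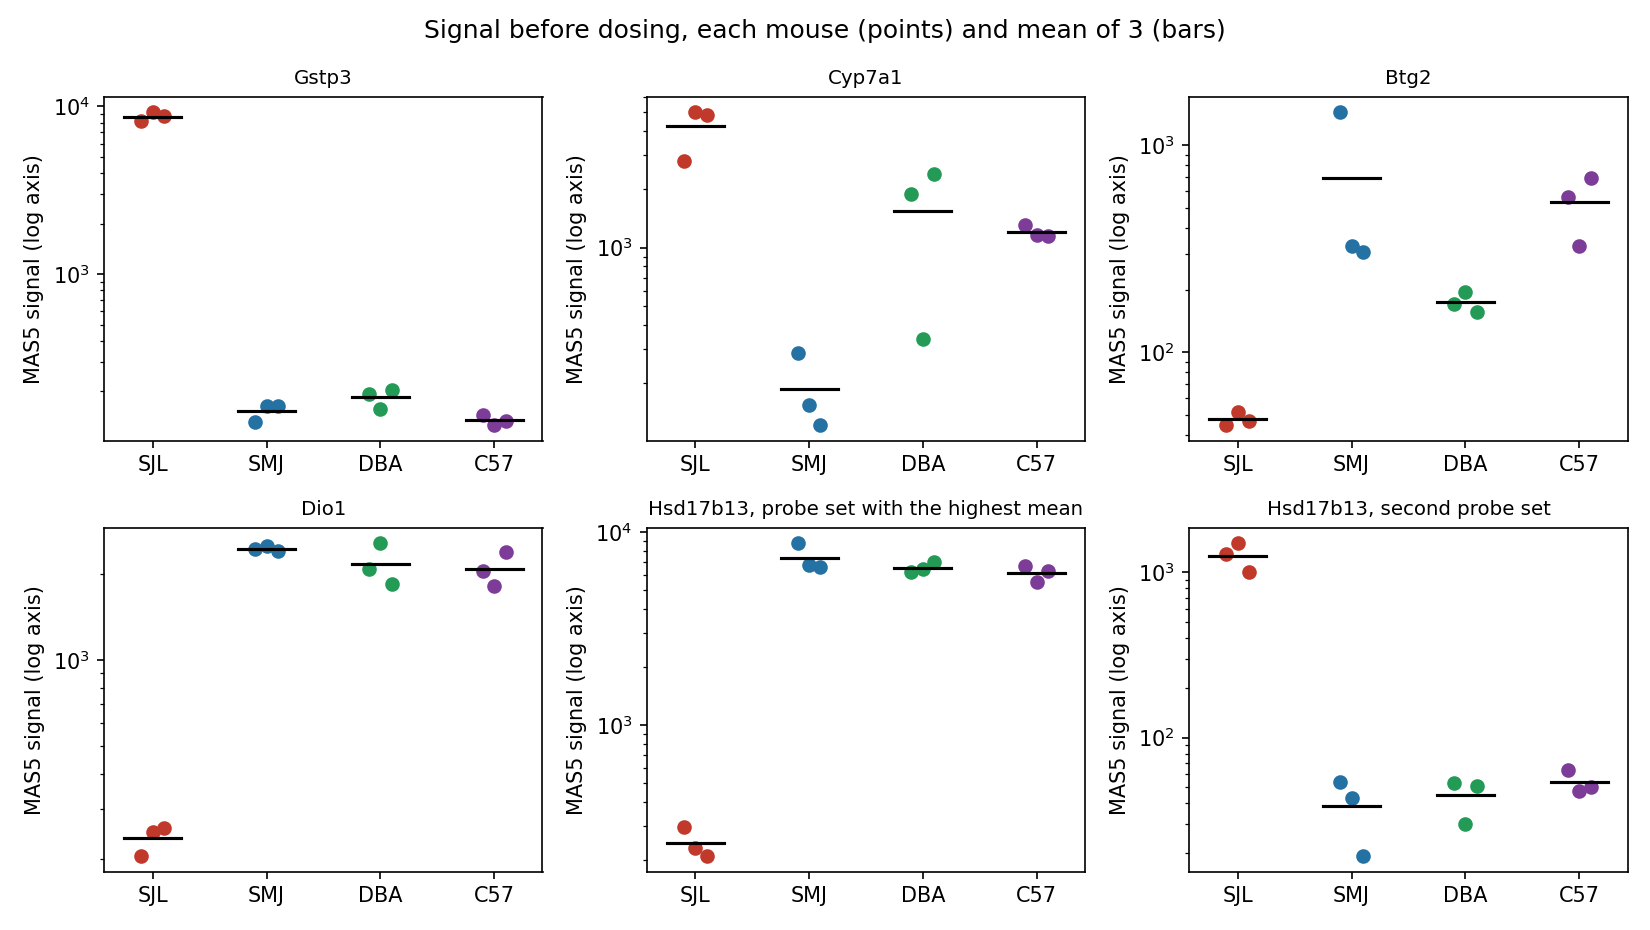
MAS5 signal (log axis) before dosing in each mouse (points) and the mean of 3 mice (bars) for SJL, SMJ, DBA and C57: Gstp3, Cyp7a1, Btg2, Dio1, and Hsd17b13 by both of its probe sets. The probe sets of Hsd17b13 go opposite ways, with SJL at 245.5 against 6154 to 7340 for the first and at 1262 against 38.7 to 53.8 for the second.

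By list, SJL at 0 h had 6 of 17 methionine cycle and sulfur amino acid genes higher and none lower (11 adjusted over the list alone). This list passed camera (adjusted p = 3.56e-05, and 0.0588 with an estimated correlation). Among the higher genes were the glycine methyltransferase Gnmt at 0.76 ± 0.14 and Cth, which makes cysteine from cystathionine, at 0.87 ± 0.19 (adjusted p = 0.0563 without SJL2). Of 13 heat shock proteins 6 were lower (7 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with Hspb1 at -2.28 and Hsp90aa1 at -1.12. Of 21 genes of fatty acid oxidation and PPARA targets 5 were lower (6 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation). Of 23 NRF2 target genes 1 was higher, Gclm, the regulatory subunit of glutathione synthesis, at 0.42, and 4 were lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.0298, and 0.354 with an estimated correlation). The lower ones included the glutathione transferase Gsta2 at -1.20, and without SMJ56 and SJL39 this list had an adjusted p of 0.0739. Of the 13 bioactivation and conjugation genes 2 were lower (2 adjusted over the list alone, camera adjusted p = 0.425), the p450 enzyme Cyp3a13 at -1.23 and the glutathione synthetase Gss at -0.44. Cyp2e1 differed by 0.13 (adjusted p = 0.716) and Bhmt2 by 0.30 (adjusted p = 0.183). Of 20 acute phase proteins 4 were higher (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.465 with an estimated correlation). Serum amyloid Saa2 was higher by 3.94 ± 0.86, where the levels were 7501 ± 3170 in SJL and 4435 ± 6520 in C57. Markers of other liver cells were higher in SJL as well. These were 8 of 13 Kupffer cell markers (11 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation) and 5 of 11 endothelial markers, with 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0588 with an estimated correlation). So were 4 of 11 stellate cell markers (5 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Many of these calls ended without some single array: 5 of 6 in the methionine cycle list, 3 of 6 heat shock, 4 of 5 fatty acid oxidation, 3 of 5 NRF2, 3 of 4 acute phase, 4 of 8 Kupffer cell, 2 of 6 endothelial and 3 of 4 stellate cell calls.

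To ask whether SJL responded otherwise than the sensitive strains, its change from 0 h was set against the mean change of the other 3. The same 0 h mice enter this contrast with the opposite sign to the comparison before dosing. Genes high in SJL at 0 h therefore tend to differ downward here, genes low at 0 h upward, and the 2 results are not independent. At 3 h the responses differed in 651 genes: 303 changed more upward and 348 more downward in SJL. Of the genes of fatty acid oxidation and PPARA targets, 17 of 21 fell in SJL, with a median change of -0.68, against medians of 0.06, 0.20 and 0.17 in SMJ, DBA and C57. In the direct test of the difference 18 of 21 were lower in SJL (19 adjusted over the list alone), with a list median of -0.897, and the list passed camera (adjusted p = 2.29e-24, and 0.00809 with an estimated correlation). Of the 18 calls 5 ended without some single array, and 15 were left without SJL1. Hepatocyte secreted proteins also differed downward, with a list median of -0.34 (camera adjusted p = 5.68e-05, and 0.323 with an estimated correlation). Of these 12 genes only the apolipoprotein Apob passed (-0.70; 1 adjusted over the list alone), with 7 at an unadjusted p under 0.05, and after quantile normalization the list's direction turned (adjusted p = 0.792). Ehhadh, the peroxisomal bifunctional enzyme of fatty acid oxidation, differed by -1.69 ± 0.19 (adjusted p = 8.24e-06), from 9067 ± 2000 to 3258 ± 464 in SJL and from 9263 ± 1070 to 11100 ± 2160 in SMJ. The lipid droplet protein Plin2 differed by -1.37 ± 0.17, Angptl4, an inhibitor of lipoprotein lipase, by -1.20 ± 0.19 and the mitochondrial acylcarnitine carrier Slc25a20 by -0.98.

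**Figure D4:**
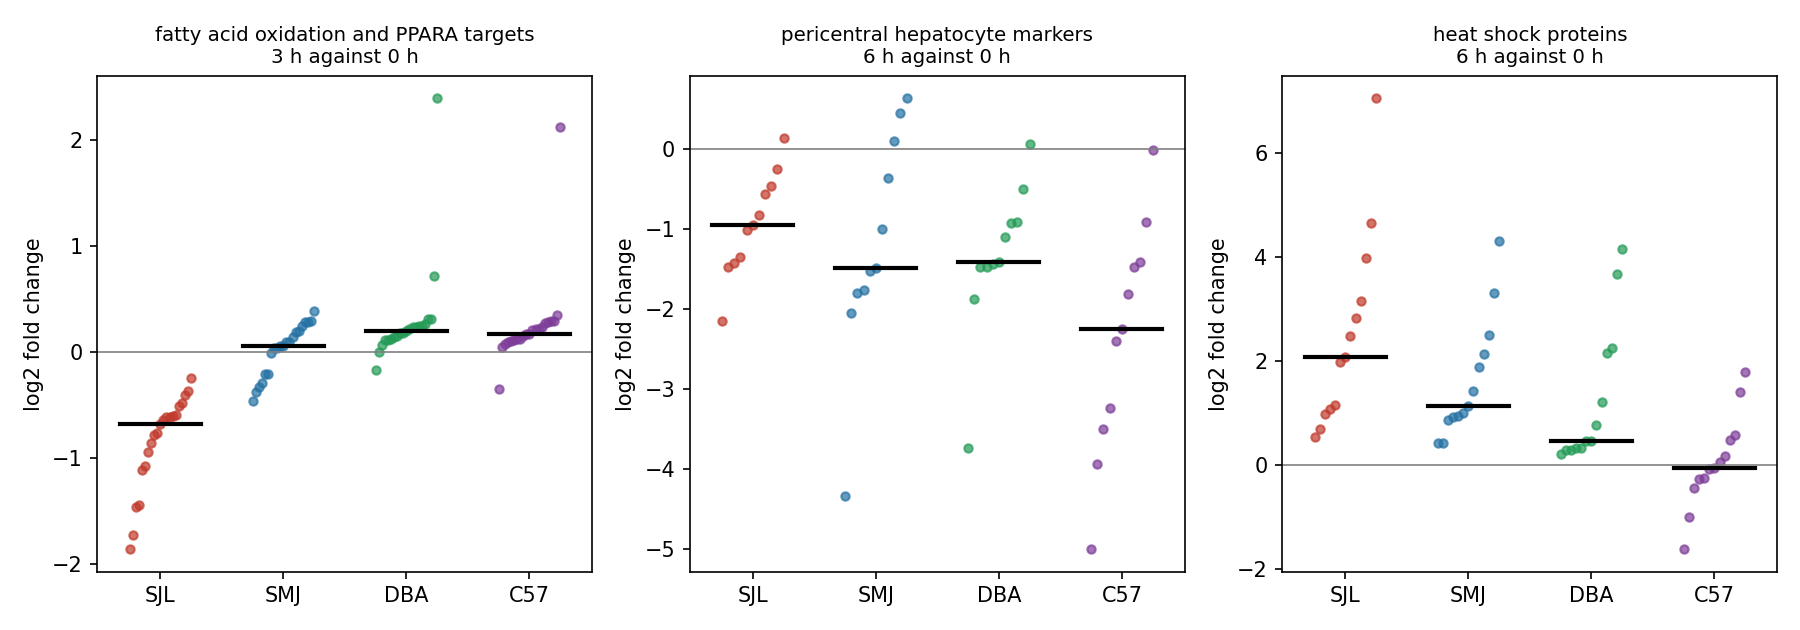
Log2 change from 0 h for the genes (points) of 3 lists in each strain, with the list median as a bar: fatty acid oxidation and PPARA targets at 3 h, pericentral hepatocyte markers at 6 h and heat shock proteins at 6 h. The medians were -0.68, 0.06, 0.20 and 0.17 for the first list, -0.95, -1.49, -1.42 and -2.26 for the second and 2.07, 1.13, 0.47 and -0.06 for the third, in the order SJL, SMJ, DBA, C57.

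Further metabolic genes turned down in SJL at 3 h relative to the other strains. Of 14 genes of bile acid synthesis and transport 4 differed, all downward (8 adjusted over the list alone; adjusted p = 0.0338 with an estimated correlation). Cyp7a1 differed by -3.41 ± 0.64, from its high level of 4234 ± 1230 to 757.2 ± 508, the sterol hydroxylase Cyp8b1 by -1.08 and the phospholipid exporter Abcb4 by -1.14. Nr1h4 differed by -0.76, with an adjusted p of 0.0758 or 0.053 without SJL39 or SJL40 and of 0.0605 or 0.0608 without SJL2 or SJL4. Of 13 genes of glucose production and use 3 differed downward (4 adjusted over the list alone; adjusted p = 0.092 with an estimated correlation). They were glucose-6-phosphatase G6pc, by -2.87 ± 0.45, pyruvate carboxylase Pcx by -0.95 and Pck1, the control enzyme of gluconeogenesis, by -0.88. In the methionine cycle list 2 of 17 differed (5 lower adjusted over the list alone; adjusted p = 0.092 with an estimated correlation). Bhmt2 differed by -0.99 ± 0.20 (adjusted p = 0.00482), from 4062 to 2279 in SJL. Bhmt differed by -0.74 ± 0.18, a gene whose adjusted p was 0.0563 without SJL2 and 0.0525 without SJL40 and whose call was lost after quantile normalization. G0s2 differed by -4.12 ± 0.58, the lipid transporter Mfsd2a by -2.85, the urea cycle enzyme Ass1 by -2.72, the nicotinic receptor subunit Chrna2 by -3.20 and Dio1 by -2.83 ± 0.26, from 237.4 ± 28.2 to 33.9 ± 13.4. The muscle genes Tnnc2 and Trim63 differed by -5.51 and -3.97. Their calls ended without any of 16 and 11 single arrays, with adjusted p values up to 0.129 (without SJL40) and 0.116 (without SJL2). Their signals at 3 h in SJL39 and SJL40 were 2.85 and 1.29 for Tnnc2 and 0.541 and 0.856 for Trim63, around or below the 10th percentile of all values, so the sizes depended on the offset. They were -6.16 and -4.93 with an offset of 1, and -4.38 and -2.69 with the 25th percentile, where the call of Trim63 ended (adjusted p = 0.0533). The median log2 level of skeletal muscle markers ran from 6.97 to 7.42 in SJL at 0 h and from 3.00 to 5.54 at 3 h. Tnnc2 and Trim63 are among these markers, and muscle tissue in some samples was not tested as their source. Aff3, a transcriptional regulator, differed by -2.78 (-3.25 and -1.98 with these offsets), with an adjusted p of 0.0854 or 0.12 without SJL39 or SJL40 and of 0.0557, 0.0802 or 0.083 without SJL1, SJL2 or SJL4.

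Some inflammatory genes changed more upward in SJL at 3 h. Of the 21 cytokines, chemokines and adhesion molecules 5 differed upward (11 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), with a list median of 1.63. Icam1, an adhesion molecule for leukocytes, differed by 2.56 ± 0.51 and endothelial selectin Sele by 3.18 ± 0.73. Socs3 differed by 2.11 (adjusted p = 0.064 without SJL40), and Ccl7 by 2.90 (adjusted p = 0.0804 without SJL39, and 0.0544 or 0.0881 without SJL2 or SJL4). Cxcl1 differed by 3.76, a call that ended without any of 11 single arrays, with adjusted p values up to 0.0926 (without SJL4). Among signalling genes the NF-kB subunit Nfkb2 differed by 3.69 ± 0.76, its cofactor Bcl3 by 3.18 ± 0.63 and the pattern receptor Tlr2 by 3.22 ± 0.76. Cish, a feedback inhibitor of STAT5 signalling, differed by 3.08 ± 0.33 (adjusted p = 3.64e-06), from 84.2 ± 11 to 1012 ± 569 in SJL, and Socs2 by 3.52 ± 0.64, from a low 100.1 ± 21.7 to 1198 ± 774. Serpina7 and Serpina9, both of the serpin family, differed by 5.0 and 3.90, where Serpina7 stood at 207.6 ± 263 in SJL and 0.932 ± 0.611 in SMJ at 3 h. The SMJ level lay below the 10th percentile of all values, 2.77, so the size of the difference depended on the offset. It was 5.59 for Serpina7, 4.39 for Serpina9 and 3.75 for Sele with an offset of 1, and 3.97, 3.03 and 2.22 with the 25th percentile. The SJL mice at 3 h were unlike each other: Tlr2 read 1590, 134.9 and 77.7 in SJL39, SJL40 and SJL42, Icam1 read 2606, 943.2 and 328.1 and Fos read 178.2, 1397 and 7125. Without SJL1 or SJL2 the count of 651 became 418 or 406.

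At 6 h the SJL response differed from that of the sensitive strains in 49 genes, 38 upward and 11 downward. Heat shock proteins led: 4 of 13 differed upward (10 adjusted over the list alone), with a list median of 1.52, and the list passed camera (adjusted p = 1.94e-15, and 0.0367 with an estimated correlation). The same list had a median of -0.746 in SJL against the other strains at 0 h, so its low level before dosing is part of this difference. Hsp90aa1 differed by 1.52 ± 0.25 (adjusted p = 0.0128), from 2299 ± 204 at 0 h, the lowest group mean, to 9767 ± 1840 in SJL and from 5176 ± 446 to 4373 ± 365 in C57. It rose at 6 h in SMJ by 1.13 (adjusted p = 0.000434) and in DBA by 0.77 (adjusted p = 0.0185). Hspa1b differed by 3.07 ± 0.69, Hsph1 by 2.49 ± 0.52 and the co-chaperone Bag3 by 1.76 ± 0.40. Of 11 pericentral markers none differed over all genes by limma (5 upward adjusted over the list alone and 5 at an unadjusted p under 0.05). As a list, with a median of 0.65, they passed camera upward (adjusted p = 0.000657, and 0.102 with an estimated correlation). The fry adjusted p was 0.00734. Among single genes, the phosphatase Dusp8 differed by 2.72, Sox9, a bile duct transcription factor, by 1.61, the nuclear RNA Neat1 by 1.62 and the chaperone partner Chordc1 by 1.25. Downward differences were those of Nr4a1, an orphan receptor and immediate early gene (-2.55), Noct (-1.91) and Rgs1, a brake on chemokine receptor signalling (-1.90).

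These 6 h differences rested on single arrays. Without SJL45 the count fell from 49 to 1, and the adjusted p became 0.0622 for Hsp90aa1, 0.06 for Dusp8, 0.0881 for Chordc1, 0.211 for Bag3, 0.159 for Noct and 0.179 for Hspa1b, Hsph1, Neat1, Sox9, Nr4a1 and Rgs1. No other single array ended the calls of Hsp90aa1 and Dusp8, whereas that of Chordc1 ended without any of 4 arrays and that of Hsph1 without any of 7. Those of Rgs1, Neat1 and Sox9 ended without any of 12, 16 and 19, and those of Hspa1b, Nr4a1, Bag3 and Noct without any of 28, 27, 30 and 30. The count became 18 without SJL44, 11 without SJL1 or SJL2, 12 without SJL4, and between 25 and 32 without SMJ57, SMJ58, SMJ103, DBA113, DBA169, C57180, C57233 or C57236. Arrays taken at 3 h, which are not part of this comparison, moved it too: 78 genes differed upward and 23 downward without SJL39, and the count became 74 without SJL42 and 29 without C57226, C57230 or C57231. The same contrast for another strain gave 1 gene for SMJ, 44 for DBA and 0 by limma for C57 at 3 h (1133 at an unadjusted p under 0.05), and 325, 98 and 654 at 6 h.

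Over both times together, 1130 genes had responses that differed between any of the strains. The largest moderated F values belonged to Dusp16, a phosphatase of stress kinases (34.7, adjusted p = 4.76e-07), which rose by 1.54 in DBA and 1.30 in SMJ at 6 h and fell by 0.81 in C57. Blvrb, a biliverdin reductase (F = 30.7), and the ribonuclease Rnase4 (F = 26.1) fell by 1.34 and 1.89 in C57 at 6 h. Dio1 (F = 30.2) and Tlcd4 (F = 29.3) fell by 2.79 and 1.28 in SJL at 3 h.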

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

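The tests on SMJ56, on SJL39 and on splits with the mean time course removed were chosen only after the result was seen. The tests on second probe sets and the other splits were chosen before.

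Stress genes stood high in 1 mouse sampled before dosing. In SMJ56 the signal of Atf3 was 953 against 98.2 and 140.6 in SMJ57 and SMJ58, that of Hmox1 5481 against 447.4 and 561.1, and that of Fos 2523 against 76.8 and 79.6. If the array were that of a 3 h mouse under a 0 h label, its slope on the SMJ response over 141 genes that responded in the other strains would be near that of the SMJ mice at 3 h, each taken on the response of the other 2 (0.837 to 1.03). It was 0.617 (bootstrap interval over genes 0.537 to 0.682), lower than in these 3 mice and in those of the other strains at 3 h (range over mice 0.767 to 1.05). The bootstrap interval covers the genes of 1 array and does not measure the spread between mice. Also, 3 mice give little measure of that spread, and the rule for this test was changed after its value was known. On the first principal component SMJ56 (-15.2) lay nearer to SMJ95 at 3 h (-17.1) than to SMJ57 and SMJ58 (4.98 and 8.52), so a 3 h mouse with a weaker response was not excluded. An array of another strain is argued against by the genes that separate SMJ: on a scale where the other strains stood at 0 and the other SMJ mice at 1, the median over 317 genes was 0.754 (bootstrap interval over genes 0.703 to 0.797). A stress of this mouse before sampling may be a candidate explanation too, and no biological explanation was tested, since the design gives no group for it.

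The 3 h response of SJL differed from that of the other strains, and the array of SJL39 had the lowest weight of the 36 (0.264). For fatty acid oxidation and PPARA targets the median difference was -0.897 with that array and -0.724 without it (p = 0.000353 with an estimated correlation in limma's camera, 15 of 21 lower), which argues against SJL39 as the whole cause. For cytokines, chemokines and adhesion molecules the median went from 1.63 to 1.39 (p = 0.149 with an estimated correlation in limma's camera, 3 of 21 higher), and SJL39 could not be excluded. Without SJL39 the count of genes was 700, of which 445 were among the 651. A difference of the SJL strain in its response is consistent with the first list and stays open as a hypothesis, but with 1 resistant strain it was not tested against resistance.

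Genes differed between SJL and the other strains at 0 h, where a sequence variant under the probes may pass for a difference in expression. Among genes higher in SJL by at least 2-fold, a second probe set showed the difference for 64.62% (42 of 65), against 90.65% (97 of 107) for genes higher at 6 h (Fisher's exact p = 4.47e-05). This is what variants under the probes would give for part of the genes, and so would the smaller number of arrays at 0 h. Among genes lower in SJL the shares were 56.06% (37 of 66) and 62.79% (27 of 43; Fisher's exact p = 0.553), too few to decide. Strain differences in expression stay open, and for Hsd17b13, with probe sets going by -4.75 and 4.75, the values do not show which way expression differed.

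Other splits of the arrays were compared with the real one. For the mean change at 3 h 1 of 100 splits, the real one, gave as many genes as 1012, with 138 in the highest other. It was 1 of 100 for the change at 6 h (4658 against 1336), 1 of 100 for that from 3 h to 6 h (2356 against 436), 1 of 100 for any difference between strains (1130 against 396) and 1 of 100 for SJL at 0 h (1727 against 785). Each of these real counts was above every other split drawn, and 1 of 100 is the smallest share that these splits can give. The splits for SJL at 0 h mixed mice of strains that differ (1352 genes for SMJ, 1462 for DBA and 1717 for C57 against the others). They show that strains differ, not that SJL stands out. In the SJL response difference 6 of 100 splits gave as many at 3 h (651, highest other 1157) and 6 of 100 at 6 h (49, highest other 1130), so chance was not excluded. Splits with several times the real count point to a structure of the samples, since these splits mixed times and so carried the common time course. With the mean time course removed, 1 of 100 gave as many at 3 h (651 against 53), at 6 h (49 against 24) and for any difference between strains (1130 against 14).

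For a single strain 3 mice against 3 make 10 splits, too few for a share under 0.05; in each comparison 1 of the 10, the real one, reached its count. The real count and the highest other were 1424 and 3 for SJL at 3 h, 982 and 1 for SJL at 6 h, 24 and 3 for SMJ at 3 h and 3009 and 1 for SMJ at 6 h. They were 204 and 2 for DBA at 3 h, 1767 and 1 for DBA at 6 h, 40 and 1 for C57 at 3 h, and 1442 and 1 for C57 at 6 h.

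Differences between groups in the response, by the test of the difference itself, were found for 651 genes in SJL at 3 h, 49 in SJL at 6 h and 1130 between any strains. At 3 h the SJL response exceeded the others for Serpina7 by 5, Serpina9 by 3.90, Cxcl1 by 3.76, Nfkb2 by 3.69, Socs2 by 3.52, Tlr2 by 3.22, Sele and Bcl3 by 3.18, Cish by 3.08 and Ccl7 by 2.90. It lay below them for Tnnc2 (-5.51), G0s2 (-4.12), Trim63 (-3.97), Cyp7a1 (-3.41), Chrna2 (-3.20), G6pc (-2.87), Mfsd2a (-2.85), Dio1 (-2.83), Aff3 (-2.78) and Ass1 (-2.72). Tnnc2 and Trim63 are skeletal muscle genes, and muscle markers also varied between arrays of the same group. The calls of Ccl7, Cxcl1, Tnnc2, Trim63 and Aff3 ended without single arrays, with adjusted p values up to 0.0881 and 0.0926 (both without SJL4), 0.129 (without SJL40), 0.116 (without SJL2) and 0.12 (without SJL40). For Serpina7, Serpina9, Sele, Tnnc2, Trim63 and Aff3 the size of the difference depended on the offset. With the 25th percentile as the offset the call of Trim63 ended (-2.69, adjusted p = 0.0533).

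At 6 h the SJL response exceeded the others for Hspa1b by 3.07, the receptor gene Adgrg2 by 2.99, Dusp8 by 2.72, Hsph1 by 2.49, Bag3 by 1.76, Neat1 by 1.62, Sox9 by 1.61, Hsp90aa1 by 1.52, the uracil glycosylase gene Ung by 1.36 and Chordc1 by 1.25. It lay below them for Nr4a1 (-2.55), Noct (-1.91), Rgs1 (-1.90), Slc25a25 (-1.28), Ppl (-1.25), Syt3 (-1.21), Nckap1l (-0.97) and Zfp281 (-0.89). Without SJL45 the count of 49 became 1, and each of these calls ended without at least 1 single array. The highest adjusted p was 0.11 for Adgrg2 (without SJL1), 0.0879 for Ung (without SJL4), 0.0888 for Syt3 and 0.0869 for Nckap1l (both without SJL1), 0.172 for Zfp281 and 0.179 for Slc25a25 and Ppl (these without SJL45). The size for Adgrg2 was 3.48 with an offset of 1 and 2.12 with the 25th percentile.

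The largest moderated F values for a difference between strains were 34.7 for Dusp16, 30.7 for Blvrb, 30.2 for Dio1, 29.3 for Tlcd4 and 26.1 for Rnase4. By list, the SJL response had a median difference of -0.897 for fatty acid oxidation and PPARA targets and of -0.504 for bile acid synthesis and transport at 3 h, and of 1.52 for heat shock proteins at 6 h. Among 5063 probe sets without a single gene name, which no comparison used, 1028 had changed at 6 h (573 higher and 455 lower), 341 at 3 h, and 255 differed in SJL at 0 h.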

How the results depend on the processing

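Leaving out SMJ56 and SJL39, and leaving out single arrays of the groups not compared, were tried only after the data had been seen. The other settings were chosen before. Counts that moved by over 1.5 times are given by setting. Without a filter on low signals, where more genes were tested, the SJL response difference at 6 h had 12 genes. With the filter at the 75th percentile, where fewer were tested, it had 136, and SMJ at 3 h 42. With array weights SJL had 1563 genes at 6 h, SMJ 192, DBA 411 and C57 95 at 3 h, and the SJL difference at 6 h 282. A prior variance with a trend gave 42 for SMJ at 3 h and 91 for that difference, and testing every probe set 341 for DBA at 3 h and 111. With only the groups compared, and so fewer arrays and a spread not pooled over all groups, the counts at 3 h and 6 h were 6 and 311 for SJL, 0 by limma and 1120 for SMJ (1160 at an unadjusted p under 0.05 at 3 h with all arrays). They were 92 and 510 for DBA, and 13 and 275 for C57. Without SMJ56 and SJL39 they were 167 for SMJ and 82 for C57 at 3 h and 157 for the SJL difference at 6 h. The cause of these moves was not tested. With only the groups compared, the number of arrays and the pooling of the spread changed together.

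Of the 56 list calls, 8 held with an estimated correlation and 46 with fry. Of the same calls, 55 held with an offset of 1, 56 with the other offset, without a filter or scaled to the 75th percentile, 52 with the stricter filter, 46 after quantile normalization, 55 with every probe set and 53 without SMJ56 and SJL39. Quantile normalization turned the hepatocyte secreted proteins at 3 h and 6 h and in both response differences. It also turned Bhmt (-0.0146) and Fbp1 (-0.10) at 6 h; the cause was not tested. Scaled to the 75th percentile, the split of higher and lower became 588 and 396 for the mean change at 3 h (444 and 568) and 926 and 668 for DBA at 6 h (678 and 1089).

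Leaving out 1 array of the groups compared at a time gave 790 to 1123 genes for the mean change at 3 h, 4359 to 4652 at 6 h, 2018 to 2618 from 3 h to 6 h and 900 to 1427 for any difference between strains. By strain the ranges were 933 (without SJL1) to 1469 and 610 (without SJL48) to 785 for SJL at 3 h and 6 h and 9 (without SMJ58) to 100 (without SMJ56) and 2134 to 2857 for SMJ. They were 117 (without DBA113) to 195 and 1078 (without DBA168) to 1552 for DBA, and 12 (without C57226) to 28 and 863 (without C57236) to 1262 for C57. For SJL at 0 h the range was 1015 (without SJL1) to 1740, and for the response difference 406 (without SJL2) to 933 (without SJL42) at 3 h and 1 (without SJL45) to 64 at 6 h. Arrays of the other groups, left out in turn after the data had been seen, act through the pooled spread. Without SJL39, the highest case for each count that follows, there were 4872 genes for the mean change at 6 h, 1155 for SJL, 3311 for SMJ, 2013 for DBA and 1696 for C57 at 6 h, and 44 for SMJ, 251 for DBA and 66 for C57 at 3 h. There were 1999 for SJL at 0 h, and 78 upward and 23 downward for its response difference at 6 h, which had as few as 29 without C57226, C57230 or C57231. Of 348 calls of named genes, 249 held with each of the 36 arrays left out in turn, 346 with an offset of 1, 313 without a filter, 330 with array weights, 348 with a trend, 320 after quantile normalization, 338 scaled to the 75th percentile and 292 with only the groups compared. No paired analysis was possible because the groups share no replicate numbers and each array is a different animal. Signal over background limits the weakly expressed genes, and the number of arrays limits the precision.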

Other observations

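The tests on pancreatic and muscle markers were chosen only after the result was seen; the gene lists in the next paragraphs were fixed before.

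Of 17 genes of the circadian clock 3 rose at 3 h (3 adjusted over the list alone; camera adjusted p = 0.254, with a list median of -0.04 and a mean of 0.12). At 6 h 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.055, and 0.382 with an estimated correlation). Ciart, a repressor of the clock, rose by 1.74 at 3 h and stood 1.55 above 0 h at 6 h, Bhlhe40 rose by 0.74 and 1.44, and Nfil3, a repressor of clock output genes, by 0.59 and 0.93. In fatty acid synthesis 4 of 14 genes were higher and 2 lower at 6 h (4 and 2 adjusted over the list alone; adjusted p = 0.247), with Thrsp at 2.54, the regulator Srebf1 at 0.69 and the carboxylase Acacb at -0.57. In cholesterol synthesis 1 of 14 genes rose at 3 h (1 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation), Lss, whose call ended without any 1 of 13 arrays (adjusted p up to 0.0693, without C57231). At 6 h 2 rose (0 adjusted over the list alone by limma, with 3 at an unadjusted p under 0.05; camera adjusted p = 0.225), Sqle, which makes squalene epoxide, at 0.87, and Lss, whose call ended without either of 2 arrays (adjusted p up to 0.0532, without DBA166). In glucose production and use 2 of 13 rose at 3 h (2 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation). At 6 h 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.265). Igfbp1, which binds insulin-like growth factors, stood at 0.83 and 0.82 at the 2 times and the coactivator Ppargc1a at -0.49 at 6 h. Of 21 genes of fatty acid oxidation and PPARA targets 5 rose and 4 fell at 6 h (6 and 5 adjusted over the list alone; adjusted p = 0.368), with the hormone gene Fgf21 at 1.18 and the thioesterase gene Acot1 at -0.67. Acute phase and hepatocyte secreted proteins passed camera upward at 3 h (adjusted p = 0.00539 and 0.000255, and 0.489 and 0.354 with an estimated correlation). Over all genes 1 of 20 and 0 of 12 rose by limma (0 and 0 adjusted over the list alone), with 6 and 4 at an unadjusted p under 0.05. The first was Serpina3n at 0.37, a call that ended without any 1 of 17 arrays (adjusted p up to 0.0919, without SMJ58). After quantile normalization the adjusted p values were 0.808 and 0.75, and the secreted proteins turned direction.

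Of 11 stellate cell and fibroblast markers 4 rose and 2 fell at 6 h (4 and 2 adjusted over the list alone; adjusted p = 0.163), with the matrix gene Dcn at 0.43 and smooth muscle actin Acta2 at 0.54. Of 5 bile duct cell markers Sox9 rose at 6 h by 1.35 (1 adjusted over the list alone; adjusted p = 0.225) and was lower in SJL at 0 h by -1.47 (1 adjusted over the list alone; adjusted p = 0.449). Of 8 lymphocyte markers Ptprc, which encodes the leukocyte antigen CD45, was higher in SJL at 0 h by 0.89 (1 adjusted over the list alone; adjusted p = 0.113 with an estimated correlation, and 0.0515 by camera without SMJ56 and SJL39). Of 3 erythroid markers 1 was lower in SJL at 0 h (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.736). In SJL at 0 h, 3 of 20 immediate early genes were lower (4 adjusted over the list alone; adjusted p = 0.377 with an estimated correlation). There 2 of 14 bile acid genes were higher (4 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation), as were 4 of 12 hepatocyte secreted proteins (7 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation, and 0.0714 by camera after quantile normalization).

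Further lists passed camera in the response difference of SJL but not with an estimated correlation. At 3 h NRF2 targets had 3 of 23 genes differing upward (5 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation, and 0.0968 by camera without SMJ56 and SJL39). Heat shock proteins had 3 of 13 (4 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation). Of these 6 genes only Hsp90aa1 kept its call with each array left out in turn. The call ended without any 1 of 3 arrays for Ugdh, 4 for Bag3, 5 for Txnrd1, 9 for Osgin1 and 16 for Hspb8, with adjusted p values up to 0.0859 (without SJL1), 0.104 (without SJL42), 0.0971 (without SJL40), 0.112 (without SJL42) and 0.189 (without SJL40). Periportal markers had 2 of 10 differing downward (5 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Stellate cell markers had 2 of 11 (5 adjusted over the list alone; adjusted p = 0.0923 with an estimated correlation) and Kupffer cell markers had 1 of 13 (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.354 with an estimated correlation). Of these 5 genes only Pck1 kept its call with each array left out in turn. The call ended without any 1 of 3 arrays for Reln, 11 for Hsd17b13, whose probe sets went opposite ways at 0 h, 27 for Clec4f and 29 for Dcn. Their adjusted p values reached 0.0634 (without SJL40), 0.131 (without SJL1), 0.129 (without SJL4) and 0.176 (without SJL39). At 6 h the lists of glucose production and use, periportal, Kupffer cell and endothelial markers and hepatocyte secreted proteins passed downward, with medians of -0.36, -0.38, -0.43, -0.33 and -0.26 and adjusted p values of 0.155, 0.0823, 0.281, 0.092 and 0.354 with an estimated correlation. None of their genes differed over all genes by limma (1 higher and 4 lower, 0, 0, 2 lower and 0 adjusted over the list alone), with 5, 3, 4, 4 and 4 at an unadjusted p under 0.05. The hepatocyte secreted proteins turned direction after quantile normalization.

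Skeletal muscle genes differed between arrays, with a median log2 level of 13 markers from 3.00 to 8.50 over the 36 arrays, from 6.97 to 7.42 in SJL at 0 h and from 3.19 to 4.88 in DBA at 0 h. Within a group it ran from 3.18 to 8.44 in SMJ at 0 h and from 3.80 to 7.88 in SJL at 6 h. The response differences of Tnnc2 and Trim63, which are among these markers, cannot be told apart from this variation between arrays.

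Pancreatic genes also differed between mice of the same group: Ctrb1 read 12250 in SJL39 and 292.2 in SJL40, Prss2 10990 and 186.2, and Cela1 12400 and 325.2, genes chosen after their values were seen. In SJL the median log2 level of acinar markers ran from 11.22 to 12.20 at 0 h and from 4.51 to 9.02 at 6 h, without overlap. The ranges at these times overlapped in each other strain. Pancreatic genes may thus be among those called lower in SJL at 6 h, which was not counted. At 0 h the SJL range lay above those of SMJ (7.49 to 10.95) and C57 (4.68 to 9.21) and inside that of DBA (9.13 to 13.07). The same SJL arrays enter the comparison of strains at 0 h and both response differences. Pancreatic genes may be among the calls there too, which were not counted either. A first test asked whether acinar markers were highest in SJL39, and 0 of 19 acinar markers were above the highest of the other arrays. A second test was written after that: over the 36 arrays the median pairwise Spearman correlation of the 19 markers was 0.979 (lowest 0.936), with list medians from 3.86 to 13.64 on the log2 scale. The medians of acinar and of 4 islet markers correlated across the 36 arrays (Spearman rho = 0.692, permutation p = 2e-05; Pearson r = 0.708, permutation p = 1e-05, the smallest these permutations can give; r = 0.699 without the 2 arrays farthest from the median). Pancreatic tissue taken with the liver in some mice of every strain is a candidate source, as a hypothesis; the labels name no sort or gate that would remove it.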
